A study of Lagopus muta hyperborea with 67 samples.

How the data were processed

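The series holds 67 samples of Svalbard rock ptarmigan: 60 short-read libraries, 3 long-read libraries and 4 samples of nuclei. Per the labels' protocols, RNA of the hypothalamus and the retina was extracted with TRI Reagent and RNA of the pineal gland with a spin-column kit (RNeasy Plus Micro). Short-read libraries were strand-specific mRNA libraries for DNBSEQ, long-read libraries were made with the Kinnex full-length RNA kit, and nuclei were processed with a droplet-based 3′ kit (10x Chromium). Per the submitters' processing notes, minimap2, STAR, featureCounts, edgeR and Cell Ranger were used, with no version or role stated there.

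The short-read tables hold whole-number counts as deposited by the authors, not normalized, for each exon of each RefSeq transcript of the bLagMut1 annotation. An exon shared by several transcripts is listed for each of them, and a read that spans 2 exons counts in both. Of 689836 exon entries, 260 carried no gene and held 0.0001% of the counts; these were left out. Because the entries are exons and not transcripts, as the planned design had assumed, each of the 19871 genes was given the counts of the exons of its transcript with the highest total. For VA opsin the value is the sum of its 9 exons, which include the 4 that the authors added. The long-read table holds deposited counts of full-length reads per TALON transcript model (70783 models, 18185 genes), made by the authors from 1 library per tissue: the retina of bird 1 and the pineal gland of bird 4, both SP, and the hypothalamus of bird 23, which was under a declining photoperiod. The nuclei matrices hold deposited UMI counts per gene and barcode, made with Cell Ranger per their headers. Each was taken as an aggregate of 2 libraries of 1 PI bird. This rests on the matrix numbers, which match samples 1A and 1B of 1 bird and 2A and 2B of another. The matrices do not state it, and barcodes in them were not tied to single libraries. VA opsin is split there into 9 exon features, which were summed.

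States were compared within each tissue in 1 fit of 4 group means, over all libraries of the tissue, with edgeR 4.0.16 in R 4.3.3 (filterByExpr, trimmed-mean scaling, robust quasi-likelihood fit and test). Contrasts were PI against SP, BR against PI, PR against BR and SP against PR, beside a test over the 4 states. Tissues were compared over the mean of the states in 1 fit of 60 libraries, and the difference between 2 tissues in a state contrast was tested in that fit. P-values were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. Biological variation had a coefficient of 0.196 in the hypothalamus, 0.277 in the retina, 0.34 in the pineal gland and 0.271 over the 3 tissues. Scaling factors ranged from 0.963 to 1.06, 0.923 to 1.07 and 0.79 to 1.14; a single gene, transthyretin, held 12.3% to 27.3% of the pineal counts. Values are CPM on the scaled library sizes, with the SD over birds. Birds are separate animals. Libraries of 2 tissues with the same number come from the same bird, and deviations from the state means over 15685 genes correlated more within a bird than between birds of a state (median r 0.149 against -0.034 for retina and hypothalamus, 0.086 against -0.018 for pineal gland and hypothalamus, 0.071 against -0.016 for pineal gland and retina). With state means taken out, positive values within birds push those between birds to negative values, so the latter are no independent baseline.

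Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, adjusted over lists and contrasts of a tissue; at least 3 members had to be tested. There were 33 lists, of which 50 of 396 tests passed and 0 with an estimated correlation. The 20 lists that passed somewhere are described with their comparison. In no tissue or contrast did the lists of Mueller glia, amacrine and horizontal cells, astrocytes, bipolar cells, cerebellar granule cells, choroid plexus, lymphocytes, neuronal maturation and plasticity, non-visual opsins, photoperiodic thyroid-hormone axis, pituitary hormones and pituitary markers, retinal ganglion cells, or retinoid cycle and pigment epithelium pass (13 lists). Symbols were matched to the annotation; for example 11 of 23 non-visual opsins, 13 of 19 heat shock genes, 22 of 26 clock genes and 27 of 36 phototransduction genes were found. Genes named in the text were chosen by a rule. It takes, per tissue and contrast, the 4 largest rises and the 4 largest falls among genes that pass, have a symbol, a mean log2 CPM of at least 1 and 1 direction in every fit with a bird left out. It adds VA opsin, passing members of the lists of the thyroid-hormone axis, non-visual opsins and melatonin, the genes TSHB, DIO2, DIO3, GNRH1 and NPVF in the hypothalamus, and the 2 to 4 members with the smallest p of every other passing list. Between tissues it takes the 4 largest in each direction and all non-visual opsins. Some genes that the rule takes are not reported here.

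The upstream share was tested over states by permutation (100000 resamples, two-sided) in libraries with at least 10 counts of the gene, and between tissues within birds by sign flips. Intervals are exact (Clopper-Pearson for shares, Poisson for counts) at 95%. Nuclei with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs were kept (30837 of 30881 and 37922 of 38009 barcodes). The automatic doublet threshold of Scrublet marked 1 and 4 nuclei, so the top 5% of scores were removed instead (1542 and 1897), which was decided after seeing the data. The 65320 nuclei left (29295 and 36025, median 3248 and 3241 UMIs) were clustered in scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1; igraph 0.11.9) into 33 clusters, named only from fixed markers with at least 3 detected. Permutations and intervals used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1.

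The groups, tests, lists, markers, the rule for named genes and the first set of alternatives were fixed before the data were examined. That set was DESeq2 1.42.0, size factors, other filters, only the 2 groups of a contrast, each bird left out, the level of W-chromosome genes (96 genes; sex is not in the labels), 1 surrogate variable (sva 3.50.0), the bird as a term, estimated correlation, other minimum counts and other clustering settings. Alternatives added after seeing the data were other gene summaries (distinct exons, the single highest exon), fits without or with a term for 5 retina libraries with high last-exon density (from 8225 genes with at least 6 exons), a fit without the pineal library of bird 22, which has a high last-exon density, and fits without transthyretin.

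The test of PI against SP in each tissue, 1 tissue contrast and 1 difference between tissues were checked on simulated counts in which 200 genes were changed; the other contrasts were not simulated. For PI against SP the share of changed genes recovered at folds of 1.5, 2 and 4 was 71.6%, 95.5% and 98.5% in the hypothalamus (15375 genes), 53.7%, 79.1% and 100% in the retina (15136 genes) and 6%, 49.3% and 92.4% in the pineal gland (14847 genes). For retina against hypothalamus it was 82.1%, 100% and 100% (16195 genes) and for the difference between these tissues in BR against PI 17.9%, 50.7% and 87.9% (16221 genes). Unchanged genes called numbered 7, 7, 4, 13 and 4. A heat shock list shifted by -0.5 was recovered in the 3 tissues in PI against SP with 0 of the other lists called. The simulated genes varied independently, with no correlation between genes, no bird effect and no libraries of high last-exon density. These counts of false calls therefore do not carry over to the real libraries.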

Results

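Svalbard rock ptarmigan (Lagopus muta hyperborea), a grouse of the high Arctic, were profiled in the hypothalamus, the retina and the pineal gland. The birds were in 4 seasonal states, named SP, PI, BR and PR in the labels, which do not spell them out. The series asks how transcript variants of vertebrate ancient (VA) opsin, a light-sensitive receptor of the opsin family, differ between these tissues and states. Short-read libraries came from 22 birds in the hypothalamus and the retina (SP 6, PI 7, BR 4 and PR 5) and from 16 of them in the pineal gland (SP 4, PI 4, BR 3 and PR 5). The deposited tables held 74.3 to 108 M (mega) exon counts per hypothalamus library, 91.55 to 115.5 M per retina library and 77.7 to 96.8 M per pineal library. Reduced to 1 transcript per gene, 23.3 to 36.7 M counts per library remained in the hypothalamus, 27.0 to 36.8 M in the retina and 34.9 to 44.7 M in the pineal gland. Full-length transcripts were read in 1 library per tissue (679289 reads in the hypothalamus, 668687 in the retina and 323868 in the pineal gland). Nuclei of the hypothalamus of PI birds were counted in 4 samples that were deposited as 2 matrices.

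VA opsin (LOC125692885, annotated as opsin-VA-like) was highest in the hypothalamus, intermediate in the pineal gland and lowest in the retina. Scaled across the 3 tissues, its counts-per-million value (CPM) was 12.3 ± 2.16 CPM (SD, n = 22) in the hypothalamus, 8.34 ± 3.50 CPM (SD, n = 16) in the pineal gland and 2.58 ± 0.927 CPM (SD, n = 22) in the retina. The retina was lower than the hypothalamus by a log2 difference of -2.31 (SE 0.14, adjusted p = 2.0e-21). The pineal gland was lower than the hypothalamus (log2 difference -0.63, SE 0.15, adjusted p = 0.000104). It was higher than the retina (1.69, SE 0.15, adjusted p = 1.4e-15). RNA had been extracted with another kit from the pineal gland than from the other 2 tissues, so kit and tissue cannot be told apart there. The value is a sum over exons, of which the tissues use different ones, so level and exon use are not fully separated by it.

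The use of exons at the start of the gene also differed between the tissues. The deposited tables list the exons of the annotated transcript together with 4 entries that the authors added, which include 3 exons upstream of the annotated start. The share of upstream exon 2 in the sum of upstream exon 2 and annotated exon 2 was 92.1% ± 4.31 (SD, n = 22) in the hypothalamus, 63.2% ± 15.6 (SD, n = 22) in the retina and 1.63% ± 2.29 (SD, n = 16) in the pineal gland. Pooled over birds these shares rest on 1387 of 1506 counts, 215 of 335 counts and 16 of 961 counts. The counts were not scaled for exon length, so the share compares tissues and does not give the share of transcripts with each start. Within birds the retina was lower than the hypothalamus by -28.9 percentage points (SD 14.7, lower in 22 of 22 birds, two-sided permutation p = 1e-05 from 100000 drawn sign flips). The pineal gland was lower than the hypothalamus by -90.2 points (SD 4.91, 16 of 16 birds) and lower than the retina by -62.8 points (SD 13.7, 16 of 16 birds), each with a permutation p of 3.1e-05 over all sign flips. These are the smallest p-values that the sign flips can give. Upstream exon 3 had 13.1 ± 5.17 counts per 100 counts of upstream exon 2 in the hypothalamus (SD, n = 22) and 14.1 ± 13.5 in the retina (SD, n = 22), and no count in the pineal gland. There upstream exon 2 had 16 counts in 7 of 16 libraries, too few to tell its ratio from those of the other tissues.

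**Figure D1:**
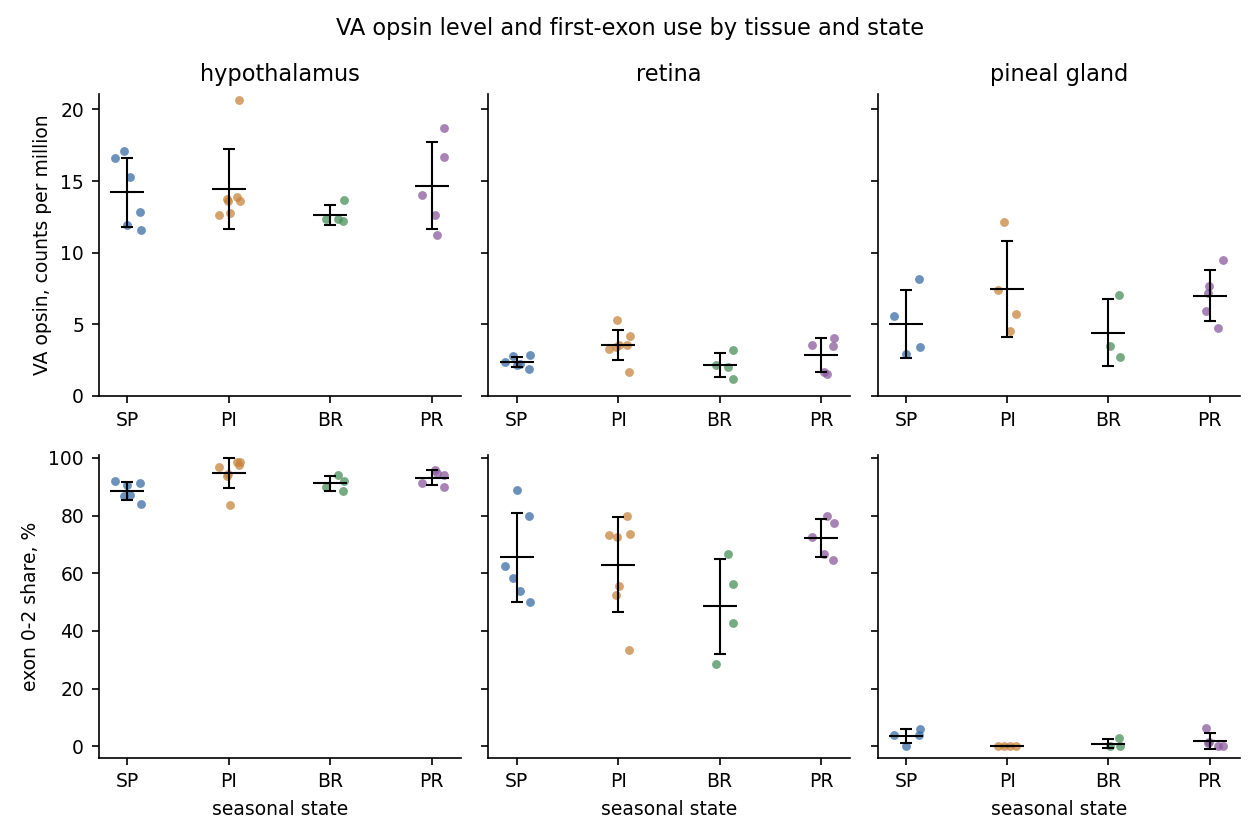
VA opsin in single birds by seasonal state in the hypothalamus, retina and pineal gland: the upper row shows the level in CPM scaled within each tissue, the lower row the share (%) of upstream exon 2, drawn as exon 0-2, in its sum with annotated exon 2. Points are birds, lines are means and bars are SD; the mean share was 92.1% in the hypothalamus, 63.2% in the retina and 1.63% in the pineal gland.

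Full-length reads placed the 2 starts on the genome. In the bLagMut1 annotation, models of VA opsin lay on the plus strand of chromosome 5 and began at position 65729823 or 65731513 (upstream start) or at 65752059 or 65752400 (internal start). Of the 21 models, 19 had an upstream start and 2 an internal start. The hypothalamus library held 216 reads of the gene, 209 of them with an upstream start (96.8%, exact binomial interval 93.4 to 98.7). The retina library held 39, of which 35 had it (89.7%, interval 75.8 to 97.1). The pooled short-read share of the retina was lower (64.2%, interval 58.8 to 69.3), on counts of 2 exons that were not scaled for length. Bird 1, the source of the long-read retina library, had a short-read share of 80% on 8 and 2 counts. The cause of the difference was not tested. In the pineal library 0 of 23 reads had an upstream start, which allows a share of up to 14.8%. There 14 reads began at 65752059 and 9 at 65752400. The 133 bp exon at 65743354 to 65743486 was included in 56 reads of the hypothalamus (25.9%), 6 of the retina (15.4%) and 0 of the pineal gland. Scaled to all long reads, the gene had 318 CPM in the hypothalamus (exact Poisson interval 277 to 363), 58.3 in the retina (41.5 to 79.7) and 71.02 in the pineal gland (45.02 to 107). The intervals of the retina and the pineal gland overlap, so these reads do not show their order. The pineal gland lay farther below the hypothalamus than in the short reads. With 1 library per tissue these are values of 3 libraries, and all intervals on counts cover counting error only. The hypothalamus library came from bird 23, under a declining photoperiod and not among the short-read birds, and the others from SP birds. Differences between the hypothalamus and the other tissues in these reads thus cannot be told apart from photoperiod or bird. NKX6-2, a homeobox gene known from oligodendrocytes, lies on the minus strand and its models begin at 65729823, the base at which the upstream models of VA opsin begin.

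**Figure D2:**
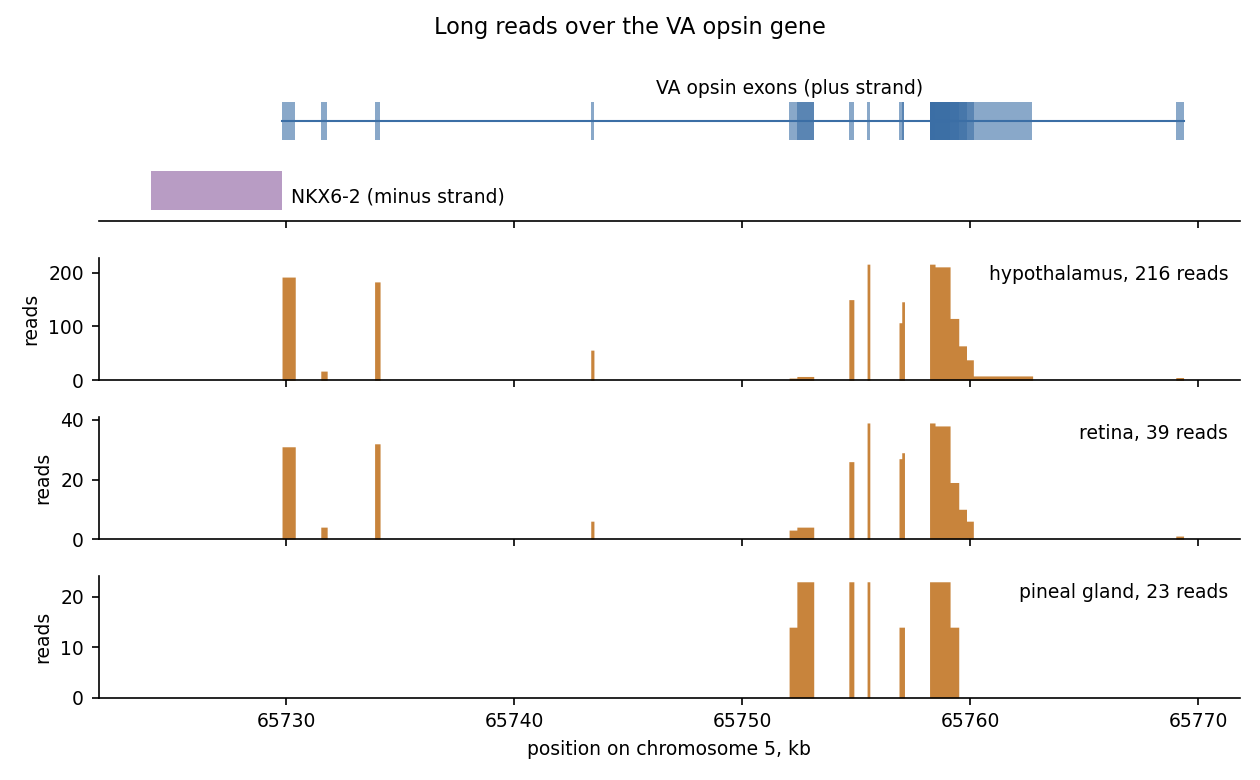
Exons of VA opsin (plus strand) and of NKX6-2 (minus strand) on chromosome 5 (position in kb) and the number of long reads that cover each VA opsin exon in the hypothalamus (216 reads), retina (39 reads) and pineal gland (23 reads). The exons upstream of the internal start carry reads in the hypothalamus and the retina and none in the pineal gland.

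Across the 4 states the level of VA opsin did not pass the test in any tissue. In the hypothalamus it was 14.2 ± 2.42 CPM in SP (SD, n = 6), 14.4 ± 2.79 in PI (n = 7), 12.6 ± 0.683 in BR (n = 4) and 14.7 ± 3.04 in PR (n = 5), scaled within the tissue. In the retina the means were 2.38 ± 0.375, 3.56 ± 1.08, 2.15 ± 0.843 and 2.86 ± 1.17 CPM in the same order. The pineal gland had 5.03 ± 2.39 CPM in SP (n = 4), 7.46 ± 3.34 in PI (n = 4), 4.43 ± 2.33 in BR (n = 3) and 7.00 ± 1.80 in PR (n = 5). Adjusted p-values of the test over the 4 states were 0.787 in the hypothalamus, 0.163 in the retina and 0.585 in the pineal gland. They were 0.781, 0.278 and 0.319 when adjusted over the list alone, that of the non-visual opsins. The contrast nearest the threshold was BR against PI in the retina (log2 difference -0.73, adjusted p = 0.0849), which passed without BR bird 15 (-0.98, adjusted p = 0.0414). No test of whether 2 tissues differ in the change of VA opsin passed, and the smallest adjusted p of the 12 was 0.566.

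The upstream share by state was 88.6% ± 3.14 in SP, 94.8% ± 5.24 in PI, 91.1% ± 2.46 in BR and 93.2% ± 2.48 in PR in the hypothalamus (SD; permutation p = 0.0545). In the retina it was 65.6% ± 15.4, 63.0% ± 16.6, 48.6% ± 16.5 and 72.3% ± 6.59 (permutation p = 0.147). In the pineal gland it was 3.52% ± 2.52 in SP, 0.91% ± 1.58 in BR and 1.83% ± 2.64 in PR, and 0 of 310 counts in PI (exact upper limit 1.18%; permutation p = 0.144). With single birds left out the hypothalamus p was under 0.05 in 4 of 22 fits and at most 0.123 (without SP bird 3). It fell to 0.0438 without SP bird 4, 0.00055 without PI bird 10, 0.0482 without BR bird 14 and 0.0456 without PR bird 18. PI bird 10 stood apart in this share (83.82%, other PI birds 93.65% to 98.68%). The pineal p was under 0.05 in 2 of 16 fits, 0.0366 without SP bird 4 and 0.0367 without PR bird 22, and at most 0.333 (without SP bird 5). The retina p was 0.0291 without 5 libraries that are described with the retina. Retina shares rest on few counts of upstream exon 2 and annotated exon 2, such as 26 of 52 over all BR birds. PR bird 21 had 4 and 1 counts of them. Part of the SD in the retina can thus be counting error.

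In nuclei of the hypothalamus VA opsin was concentrated in oligodendrocyte-like nuclei, named from markers of myelinating glia. They held 1360 of the 2553 VA opsin molecules (UMIs; 53.3%, exact binomial interval 51.3 to 55.2) in 16661 of 65320 nuclei. Their summed level was 30.6 CPM (exact Poisson interval 28.3 to 33.1) in matrix 1 and 28.9 CPM (26.8 to 31.1) in matrix 2, against 3.99 CPM (3.67 to 4.33) and 3.94 CPM (3.63 to 4.26) in all other nuclei. Neuron-like nuclei had 1.77 and 2.08 CPM, oligodendrocyte precursor-like nuclei 2.41 and 4.03 CPM. The astrocyte-like class had 8.61 and 7.65 CPM and includes a mixed cluster with oligodendrocyte genes at 16.9 CPM. The largest astrocyte-like cluster had 4.47 CPM. NKX6-2, the divergent neighbour, had 59.4 and 55.03 CPM in oligodendrocyte-like nuclei and 8.94 and 9.28 CPM in all others. By exon, all nuclei together had 674, 101 and 424 VA opsin UMIs in upstream exons 1, 2 and 3 and 397 in annotated exon 2. Upstream exon 2 was thus below annotated exon 2, the reverse of the bulk hypothalamus, and the cause was not tested.

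A VA opsin UMI was seen in 7.80% and 7.52% of oligodendrocyte-like nuclei (median depth 2485 and 2586 UMIs). Erythrocytes should lack the gene, and in the largest erythrocyte-like cluster the share was 0.31% and 0.555% (median depth 940 and 1182 UMIs). With each nucleus thinned to 1000 UMIs the shares were 2.62% and 2.61% in oligodendrocyte-like nuclei and 0.179% and 0.257% in that cluster. The level of that cluster, 3.13 CPM (1.43 to 5.95) and 4.39 CPM (2.51 to 7.12), was not below that of neuron-like nuclei. The summed values of neuron-like nuclei thus do not stand above it. That cluster is shallow and its intervals are wide, and a sum over neuron-like nuclei cannot exclude a small group of neurons with the gene. Each matrix was taken as 1 bird and no test across nuclei was made. Different clusters hold the oligodendrocyte-like nuclei of the 2 matrices (7684 of the 7799 nuclei of cluster 0 are from matrix 1 and 8767 of the 8862 of cluster 25 from matrix 2).

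**Figure D3:**
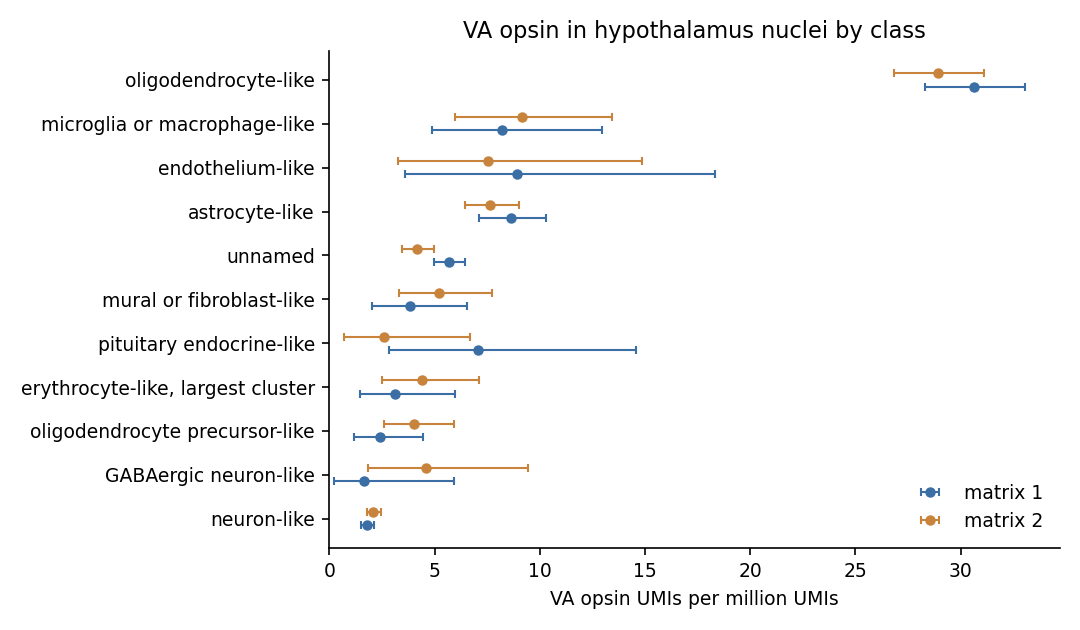
VA opsin level (CPM of UMIs) in classes of hypothalamus nuclei, named from fixed markers, in each of the 2 deposited matrices. Points are summed counts and bars are exact 95% Poisson intervals; oligodendrocyte-like nuclei had 30.6 and 28.9 CPM and all other nuclei 3.99 and 3.94 CPM.

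The 3 tissues differed in most genes. TULP1, a photoreceptor gene, had 913 ± 219 CPM in the retina and 0.0926 ± 0.331 CPM in the hypothalamus (SD, n = 22 each; log2 difference 14.31). GUCA1A and FSCN2 of photoreceptors were higher by 15.24 and 14.3. NKX2-1, a transcription factor of the ventral forebrain, had 14.5 ± 2.70 CPM in the hypothalamus and was lower in the retina (-11.27). So were UCN3 (-11.5) and TTLL10 (-11.1). ASMT, the last enzyme of melatonin synthesis, had 2575 ± 2000 CPM in the pineal gland (SD, n = 16) and 1.32 ± 0.581 CPM in the hypothalamus (10.96). NR2E3 (12.58) and RGR (11.07) were also higher in the pineal gland. HCRT, the orexin precursor, had 52.8 ± 15.4 CPM in the hypothalamus and 0.0317 CPM in the pineal gland (-10.64). NKX2-1 and VAX1 differed by -10.98 and -10.61. SLC5A7, the choline transporter, had 7.88 ± 1.94 CPM in the hypothalamus and no count in any pineal library. Against the retina, the pineal gland was higher in KL (572.5 ± 341 against 0.0849 CPM, 12.73), CCDC33 (12.41), FOXC2 (11.76) and BSX (11.44). It was lower in PRPH2 (-12.78), RD3L (-13.8) and LNP1 (-13.27). Of 16484 genes, 6700 were higher and 6657 lower in the retina than in the hypothalamus. In the pineal gland 7686 were higher and 6438 lower than in the hypothalamus, and 7287 higher and 7025 lower than in the retina. The balance of higher and lower genes depends on the scaling. With size factors in place of trimmed means, which shifted the median of all genes by -0.111 in the pineal gland against the hypothalamus, 7067 were higher and 6968 lower there, and 6957 and 7382 against the retina. With the bird as a replicate block, fitted for each pair of tissues on the birds with both, these counts were 6696 and 6958, and 6827 and 7096.

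Other opsins had their own tissue order. OPN4, melanopsin, had 40.4 ± 10.1 CPM in the retina, 0.5 ± 0.201 CPM in the hypothalamus and 0.784 ± 1.22 CPM in the pineal gland. The difference between the last 2 did not pass the test (log2 difference 0.30, adjusted p = 0.302). OPN4-like (LOC125692577, annotated as melanopsin-like) had 144 ± 17.5 CPM in the retina, 85.8 ± 18.0 in the pineal gland and 3.39 ± 0.78 in the hypothalamus. PEROPSIN-like (LOC125688685) had 146.5 ± 31.2, 39.0 ± 21.2 and 0.581 ± 0.437 CPM in the same order, and RRH 4.2 ± 3.51, 13.6 ± 11.4 and 0.588 ± 0.12 CPM. OPN3 was highest in the retina (16.0 ± 2.41 CPM) and lowest in the pineal gland (0.368 ± 0.16 CPM), with 3.21 ± 0.939 CPM in the hypothalamus. The gene annotated as pinopsin-like (LOC125688141) had 8.62 ± 2.77 CPM in the retina, 0.854 ± 0.316 in the hypothalamus and 0.180 ± 0.433 in the pineal gland. OPN5 had 0.935 ± 0.447 CPM in the retina and 0.198 CPM in the hypothalamus, and OPN5-like-b (LOC125690795) 1.40 ± 0.508 and 0.271 CPM. OPN5-like-a (LOC125688844) was higher in the pineal gland than in the hypothalamus (4.34 ± 1.04 against 3.6 ± 0.719 CPM, log2 difference 0.23, adjusted p = 0.0162). RGR was higher in the pineal gland than in the retina (250.5 ± 176 against 144 ± 47.9 CPM, 0.66, adjusted p = 0.00766). With the bird as a replicate block these 2 differences were 0.10 (adjusted p = 0.282) and 0.41 (adjusted p = 0.217) and no longer passed.

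In the hypothalamus the clock genes NR1D1, CIART, NR1D2 and PER3 rose, the clock genes CRY1 and ARNTL fell, and DIO3, the enzyme that deactivates thyroid hormone, fell in PI against SP. NR1D1 had 5.40 ± 1.41 CPM in PI (SD, n = 7) and 1.75 ± 0.508 CPM in SP (n = 6; log2 difference 1.62, adjusted p = 0.00122). CIART had 1.82 ± 0.484 against 0.548 ± 0.189 CPM (1.72, adjusted p = 0.00135), and NR1D2 (0.42) and PER3 (0.97) rose as well. Clock genes that fell were CRY1 (86.9 ± 5.45 against 116 ± 12.3 CPM, -0.42, adjusted p = 0.00746) and ARNTL, the partner of CLOCK (-0.38, adjusted p = 0.0286). DIO3 had 0.146 ± 0.0839 CPM in PI and 0.961 ± 0.444 CPM in SP (-2.68, adjusted p = 0.00746). The chloride channel CLCN2 (1.22) and the receptor ligand ALKAL2 (0.76) rose, and SBSPON fell (-1.2, adjusted p = 0.0446). In each of these 10 genes every PI bird lay on the same side of the SP median. Time of sampling was not part of the fits, and each state is 1 group of birds. For the clock genes, and for any other gene, time of sampling and state thus cannot be told apart. This holds in all contrasts and tissues, also for the genes of melatonin synthesis and reception in the retina. DIO2, the activating enzyme, had 42.1 ± 9.51 against 33.5 ± 1.81 CPM (adjusted p = 1.0), and TSHB 0.759 ± 0.277 against 0.533 ± 0.148. GNRH1 (8.67 ± 3.20 against 7.89 ± 4.05 CPM) and NPVF (145 ± 65.1 against 134 ± 34.5 CPM) did not pass either. In all 8 genes rose and 5 fell of 15491 tested. ALKAL2, ARNTL, PER3 and SBSPON missed the threshold when single birds were left out (highest adjusted p 0.0893 without SP bird 2, then 0.13, 0.195 and 0.196, each without SP bird 5). They did so in 6, 9, 20 and 17 of the 22 fits. The count fell to 6 without SP bird 1.

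Among the fixed lists in PI against SP, all 13 measured heat shock and unfolded protein genes were lower (median log2 difference -0.37, camera adjusted p = 1.1e-14). None passed over all genes and 10 did when adjusted over the list alone. HSPA2 had 202 ± 126 against 490 ± 276 CPM and HSPA5 489 ± 150 against 736 ± 187 CPM. The circadian clock list was higher (17 of 22 members, median 0.06, adjusted p = 0.00473), of which 4 rose and 2 fell, or 6 and 2 adjusted over the list alone. Visual phototransduction genes were higher (14 of 18, median 0.22 and mean 0.77, adjusted p = 0.00258; 4 adjusted over the list alone). SAG (4.53 ± 6.59 against 0.395 ± 0.22 CPM) had an SD over its mean in PI. Immediate early genes (12 of 15 lower, -0.13, adjusted p = 0.0256) and mural and fibroblast markers (9 of 9 lower, -0.17, adjusted p = 0.0362) were lower. None of these 5 lists kept its call. It was adjusted p = 0.303 with an estimated correlation for heat shock, 0.306 for the clock and phototransduction and 0.81 for the other 2.

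BR against PI brought a rise of ALDH1A1, an enzyme of retinoic acid synthesis, in the hypothalamus. It had 805 ± 162 CPM in BR (SD, n = 4) and 111 ± 50.96 CPM in PI (n = 7; log2 difference 2.86, adjusted p = 0.000194). ANKRD34B rose from 6.47 ± 1.91 to 24.5 ± 5.90 CPM (1.92, adjusted p = 0.000194). RGS2, a regulator of G-protein signalling, rose by 0.85 (adjusted p = 0.0039) and RASGRF2, an exchange factor of Ras, by 0.54 (adjusted p = 0.0185). BCL6, a transcriptional repressor, fell from 146 ± 21.8 to 76.1 ± 8.71 CPM (-0.94, adjusted p = 9.0e-05). Every BR bird lay on the same side of the PI median in these 5 genes. DIO2 had 76.9 ± 28.8 CPM in BR (0.87, adjusted p = 0.102), and DIO3 0.0171 ± 0.0197 CPM (-2.93, adjusted p = 0.162). TSHB had 1.23 ± 0.306, GNRH1 7.27 ± 2.71 and NPVF 153 ± 38.5 CPM, none past the test. Oligodendrocyte and myelin genes were lower as a list (7 of 7, median -0.33, camera adjusted p = 0.00702, adjusted p = 0.81 with an estimated correlation). Of these 0 passed over all genes and 4 adjusted over the list alone, among them CLDN11 (-0.66). In all 5 genes rose and 1 fell by edgeR, while 67 rose and 151 fell by DESeq2. RASGRF2 missed the threshold without BR bird 14, 15 or 16 (highest adjusted p 0.112). The count rose to 67 without PI bird 8 (26 rises and 41 falls), so the balance of rises and falls depends on the fit.

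From BR to PR the hypothalamus changed mainly by falls. ANKRD34B fell to 4.62 ± 1.26 CPM in PR (SD, n = 5; log2 difference from BR -2.4, adjusted p = 9.0e-05) and ALDH1A1 to 214 ± 123 CPM (-1.91, adjusted p = 0.0393). CYP19A1, aromatase, had 39.8 ± 8.26 CPM in PR and 136 ± 44.2 CPM in BR (-1.78, adjusted p = 0.000198). DIO2 fell from 76.9 ± 28.8 to 35.7 ± 7.93 CPM (-1.11, adjusted p = 0.0265), and AGTR1, an angiotensin receptor, by a log2 change of -1.04 (adjusted p = 0.0252). BCL6 rose to 120 ± 8.02 CPM (0.66, adjusted p = 0.00742). Every PR bird lay on the same side of the BR median in these 6 genes. TSHB (1.41 ± 0.688 CPM), DIO3 (0.123 ± 0.0974), GNRH1 (10.7 ± 3.86) and NPVF (177 ± 72.1) in PR did not pass the test against BR. In all 2 genes rose and 16 fell. AGTR1 and DIO2 missed the threshold without BR bird 14 (0.209 each), ALDH1A1 and BCL6 without BR bird 16 (0.196 and 0.0701). Over all 22 fits with a bird left out AGTR1 missed it in 6, DIO2 in 5, ALDH1A1 in 16 and BCL6 in 1. The count was 5 without BR bird 16.

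Oligodendrocyte and myelin genes were higher in PR than in BR (7 of 7, median 0.28, camera adjusted p = 0.0013; 2 adjusted over the list alone). So were oligodendrocyte precursor markers (6 of 7, 0.18, adjusted p = 0.0051; 1 adjusted over the list alone). Feeding and energy balance peptides were lower (21 of 24, -0.14, adjusted p = 0.00258), as was the heat shock list (10 of 13, -0.17, adjusted p = 0.0346). Reproductive neuroendocrine genes were split, 9 higher and 10 lower (median -0.09, adjusted p = 0.0374), with 1 gene that fell over all genes and 3 adjusted over the list alone. None kept its call, at adjusted p = 0.723 with an estimated correlation for myelin and feeding, 0.306 for the precursors and 0.81 for the other 2.

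In SP against PR the hypothalamus was higher in DIO3 and lower in ALDH1A1. SBSPON had 5.39 ± 1.68 CPM in SP (SD, n = 6) and 1.18 ± 0.522 CPM in PR (n = 5; log2 difference 2.18, adjusted p = 0.00046). DIO3 had 0.961 ± 0.444 against 0.123 ± 0.0974 CPM (3.01, adjusted p = 0.0163). BCL6 was higher in SP (184 ± 18.1 CPM, 0.61, adjusted p = 0.00933). ALDH1A1 (42.7 ± 10.3 CPM, -2.33, adjusted p = 0.00572) and NR1D2, at 77.3 ± 6.32 CPM in SP (-0.37, adjusted p = 0.0118), were lower. In these 5 genes every SP bird lay on the same side of the PR median. TSHB (-1.41, adjusted p = 0.145) and DIO2 (adjusted p = 0.884) did not pass. The heat shock list was higher in SP (13 of 13, median 0.39, camera adjusted p = 8.7e-10; 10 adjusted over the list alone), and so were immediate early genes (14 of 15, 0.40, adjusted p = 0.00197). Neither kept its call (adjusted p = 0.306 and 0.765 with an estimated correlation). In all 4 genes rose and 3 fell, and 48 genes differed over the 4 states. BCL6, DIO3 and NR1D2 missed the threshold with single birds left out (highest adjusted p 0.0513 without PR bird 22, 0.103 without PR bird 19 and 0.0688 without PR bird 20). The count moved to 3 without PR bird 22 and 16 without SP bird 1, and that over the 4 states to 130 without SP bird 1 and 25 without BR bird 14.

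**Figure D4:**
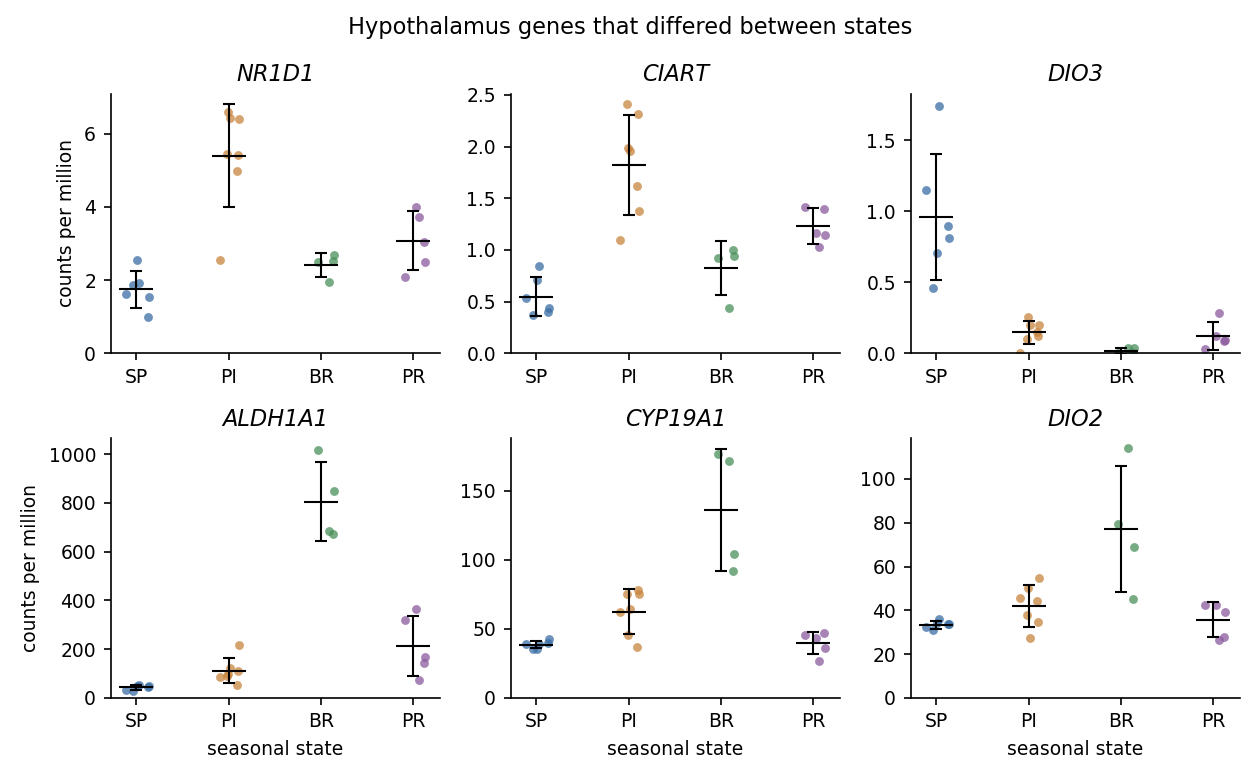
Levels (CPM) of NR1D1, CIART, DIO3, ALDH1A1, CYP19A1 and DIO2 in the hypothalamus by seasonal state. Points are birds (SP 6, PI 7, BR 4, PR 5), lines are means and bars are SD; ALDH1A1 and DIO2 have their highest mean in BR (805 and 76.9 CPM) and DIO3 in SP (0.961 CPM).

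In the retina CNGB1, PDC and GUCA1B of the phototransduction list and TPH1 fell in PI against SP. CNGB1, a subunit of the rod channel, had 615 ± 98.6 CPM in PI (SD, n = 7) and 1374 ± 129 CPM in SP (n = 6; log2 difference -1.16, adjusted p = 7.7e-06). PDC, phosducin, had 1065 ± 61.7 against 1879 ± 163 CPM (-0.82, adjusted p = 6.9e-06), and GUCA1B fell as well (-0.87). ARR3, cone arrestin, had 3848 ± 1545 against 1759 ± 199 CPM (1.13, adjusted p = 0.0107). TPH1, which starts serotonin and melatonin synthesis, fell from 428 ± 211 to 108 ± 18.6 CPM (-1.99, adjusted p = 0.000114). The melatonin receptor MTNR1B rose (0.89, adjusted p = 0.019). The exonuclease EXO1 (50.4 ± 26.8 to 4.92 ± 2.53 CPM, -3.35), WDR64 (-2.97), the hedgehog effector GLI1 (-2.42), CGA (-1.23) and the decarboxylase DDC (-0.84) fell. The kinesin KIF4A (5.50 ± 1.15 to 35.6 ± 15.8 CPM, 2.69, adjusted p = 3.4e-07), the serine synthesis enzyme PHGDH (3.12), PKHD1 (2.48) and AQP8 (2.33) rose. Every PI bird lay on the same side of the SP median in these genes except for 1 of 7 in PKHD1 and in DDC.

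In that comparison all 13 heat shock genes were lower (median log2 difference -0.57, camera adjusted p = 9.6e-08). HSPA8 (3817 ± 415 to 2154 ± 649 CPM, -0.83), HSPA4L (-0.7) and SDF2L1 (-0.57) fell, and 8 did adjusted over the list alone. Visual phototransduction genes were lower (17 of 27, -0.24, adjusted p = 0.0116), with 2 that rose and 3 that fell, or 5 and 11 adjusted over the list alone. Neither kept its call with an estimated correlation (adjusted p = 0.598 and 0.688 with an estimated correlation). In all 117 genes rose and 176 fell of 15238. The libraries of SP birds 1 and 2 and PI birds 7, 8 and 9 had a high density of counts on the last exon (log2 of last exon over 5′ part -0.25 to 0.18, against -1.18 to -0.84 in the other 17). Without them 129 genes rose and 216 fell, and AQP8 (0.137), ARR3 (0.11), CGA (0.194), DDC (0.185) and MTNR1B (0.0764) missed the threshold. With single birds left out CGA (highest adjusted p 0.0814, SP bird 1), DDC (0.12, SP bird 6), HSPA4L (0.0968, SP bird 4), MTNR1B (0.0561, SP bird 6), PKHD1 (0.0735) and SDF2L1 (0.0772, both SP bird 5) did, DDC in 14 of 22 fits. The count fell to 191 without SP bird 6.

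Of the 13 mitochondrially encoded genes 7 fell in the retina in BR against PI over all genes, 8 adjusted over the list alone and 2 over all genes without the 5 libraries with high last-exon density. All 13 were lower as a list (median log2 difference -0.50, camera adjusted p = 0.00022, adjusted p = 0.763 with an estimated correlation). Mitochondrial genes held 3.05% to 3.24% of the counts in the 3 PI libraries among those 5, 2.16% to 4.28% in the other 4 PI libraries and 2.05% to 2.8% in the BR libraries. ND6 fell (25.9 ± 11.1 CPM in BR, SD, n = 4, against 89.2 ± 29.9 in PI, n = 7; -1.78, adjusted p = 0.00742), and so did ATP8 (500.4 ± 172 against 1054 ± 151 CPM, -1.07), ATP6 (-0.97) and ND1 (-0.82). PHGDH (-3.27), BOLA3, which serves iron-sulfur cluster assembly (-2.25), JTB (-1.93), ADAMTSL5 (-1.85) and PCBD1 (-0.78) fell. OPN4, melanopsin, rose from 37.3 ± 12.7 to 57.2 ± 8.81 CPM (0.62, adjusted p = 0.0319), and ADGRG6 from 4.97 ± 1.62 to 12.7 ± 1.74 CPM (1.36, adjusted p = 0.012). The muscle genes TNNT3 (13.7 ± 20.6 against 0.294 CPM, 5.52) and ACTA1 (14.1 ± 21.6 against 1.89 CPM, 2.9) and MYOF (2.67) passed with an SD over the mean. Of the 4 BR birds 3 in TNNT3 and 2 in ACTA1 lay above the PI median, and in the other genes all 4 lay on the same side.

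In all 1224 genes rose and 1979 fell, and without the 5 libraries with high last-exon density, 3 of them from PI, 132 rose and 208 fell. ACTA1, ADAMTSL5, ADGRG6, ATP6, MYOF, ND1, OPN4 (0.16) and PCBD1 then missed the threshold. The 1224 genes had a median log2 difference of 0.54 (median SE 0.16) and without the 5 libraries 0.33 (median SE 0.11). The 1979 genes had one of -0.74 (median SE 0.21) and -0.39 (median SE 0.16). With single birds left out 12 of the 14 named genes missed the threshold and ND6 and TNNT3 did not. Without BR bird 16 the adjusted p was 0.0735 for PHGDH, 0.0542 for BOLA3, 0.0642 for JTB and ADGRG6, 0.0546 for ATP8, 0.0754 for ATP6 and 0.0941 for ND1. It was 0.107 for ADAMTSL5, 0.149 for OPN4 and 0.122 for PCBD1 without that bird, 0.239 for ACTA1 without BR bird 15 and 0.618 for MYOF without BR bird 14. Leaving out BR bird 16 alone left 27 genes, and a fit of the BR and PI libraries alone 0 (DESeq2 on all libraries 4257).

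Between BR and PR no retina gene passed by edgeR, with 478 genes at an unadjusted p under 0.05 and 43 by DESeq2; 2 passed without BR bird 16 (both lower in PR) and 2 without PR bird 21 (both higher). FKBP5, a target of the glucocorticoid receptor, had 33.1 ± 3.36 CPM in PR (SD, n = 5) and 67.03 ± 25.9 CPM in BR (n = 4; log2 difference -1.02, adjusted p = 0.224). The glucocorticoid response list was lower (9 of 12, -0.11, camera adjusted p = 0.0341). Higher in PR were endothelium markers (8 of 9, median 0.21 and mean 1.47, adjusted p = 8.9e-05; 4 adjusted over the list alone). CDH5 was at 6.75 ± 8.43 against 0.268 CPM and CLDN5 at 4.65 ± 5.92 against 0.183 CPM. Interferon response genes (12 of 15, 0.51, adjusted p = 0.000148; 2 adjusted over the list alone) and microglia and macrophage markers (10 of 10, 0.38, adjusted p = 0.000687; 1 adjusted over the list alone) were higher too. So were mural and fibroblast markers (9 of 9, 0.65, adjusted p = 0.00207) and myelin genes (7 of 7, 0.55, adjusted p = 0.0341). The erythrocyte list was called lower (adjusted p = 0.0341) while its median (0.01) and mean (0.05) lay above 0. None of the 7 lists kept its call (adjusted p = 0.347 with an estimated correlation for endothelium, microglia and glucocorticoid response, 0.598 to 0.805 for the others).

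In the retina EXO1, GLI1, WDR64 and TPH1 were higher in SP than in PR. EXO1 (50.4 ± 26.8 CPM in SP, SD, n = 6, against 4.12 ± 0.797 in PR, n = 5; log2 difference 3.61, adjusted p = 1.5e-05) was higher in SP. GLI1 (3.34), WDR64 (2.99), HSPA2 (2.26) and TPH1 (428 ± 211 against 97.8 ± 17.9 CPM, 2.13, adjusted p = 0.000133) were too. GCH1, which makes the cofactor of TPH1 (1.0), CRYM, which binds thyroid hormone (0.52), CGA (1.19) and XBP1 (0.86) were higher, and MTNR1B (-0.77) and PEROPSIN-like (-0.53) lower. Lower in SP were SERPIND1 (-4.86), FGL2 (-4.76), the efflux transporter ABCB1 (-3.73) and ANXA1 (-3.25), each with an SD over the mean in PR. FGL2 had 52.2 ± 65.7 CPM in PR. All 13 heat shock genes were higher (median 0.67, camera adjusted p = 3.2e-05). Of these 6 passed over all genes, HSPA8 and SDF2L1 among them, and 6 adjusted over the list alone. Higher as a list were also all 13 mitochondrially encoded genes (0.48, adjusted p = 8.9e-05; 3 passed, ND6, ATP8 and ATP6, and 8 adjusted over the list alone). Mural and fibroblast markers were lower (9 of 9, -1.33, adjusted p = 0.0267; COL3A1, DCN and PDGFRB passed, and 4 adjusted over the list alone). None of the 3 kept its call (adjusted p = 0.688, 0.763 and 0.688 with an estimated correlation). Every SP bird lay on the same side of the PR median except for 1 of 6 in ABCB1 and in CGA.

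In all 701 genes were higher and 468 lower in SP than in PR, and 608 in all passed without SP bird 1. Without the 5 libraries with high last-exon density 1664 passed, and ABCB1, ANXA1, CGA, COL3A1, CRYM, FGL2, PEROPSIN-like, PDGFRB and SERPIND1 did not. With single birds left out the highest adjusted p was 0.146 for ANXA1, 0.231 for COL3A1 and 0.107 for PDGFRB (all PR bird 20), 0.109 for CGA (SP bird 1) and for MTNR1B (PR bird 19). It was 0.0644 for HSPA2 (SP bird 3) and 0.0538 for SERPIND1 (PR bird 18), and ABCB1, CRYM and PEROPSIN-like missed the threshold as well. Over the 4 states 3848 retina genes differed, 2074 without the 5 libraries.

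In the pineal gland few genes passed, among them 2 clock genes and a target of the glucocorticoid receptor. FKBP5 fell from 156 ± 61.0 CPM in BR (SD, n = 3) to 42.6 ± 4.32 CPM in PR (n = 5; log2 difference -1.87, adjusted p = 0.0107), the only gene that passed in that contrast. In SP against PR the clock repressor NR1D1 had 0.640 ± 0.427 CPM in SP (n = 4) and 7.82 ± 4.14 CPM in PR (n = 5; -3.59, adjusted p = 0.0228). PER3 had 8.34 ± 2.42 against 27.7 ± 6.50 CPM (-1.73, adjusted p = 0.0228), and FIBCD1 2.01 ± 1.06 against 22.2 ± 9.88 CPM (-3.46, adjusted p = 0.0228). BCL6 (59.6 ± 9.78 against 29.0 ± 4.66 CPM, 1.04, adjusted p = 0.0228) and the chaperone DNAJB11 (147 ± 8.12 against 93.5 ± 6.29 CPM, 0.65, adjusted p = 0.0256) were higher in SP. Every PR bird in FKBP5 and every SP bird in the other 5 genes lay on the same side of the median of the group it was compared with. As in the hypothalamus, time of sampling and state cannot be told apart for NR1D1 and PER3. Melatonin synthesis genes did not pass: TPH1 had 4292 ± 5074 CPM in SP and 8169 ± 3335 CPM in PR, and AANAT 50.1 ± 59.2 and 111 ± 49.4 CPM. Of 15011 genes 2 were higher and 4 lower in SP than in PR, 1 fell in PR against BR and 9 differed over the 4 states. Each of the 6 calls was lost with some bird left out (highest adjusted p 0.0633 without PR bird 21 for FKBP5, 0.104 without SP bird 6 for FIBCD1, 0.117 for BCL6 and DNAJB11 and 0.0876 for NR1D1 and PER3 without PR bird 19), DNAJB11 in 9 of 16 fits. The SP against PR count moved from 0 without SP bird 6 to 1785 without SP bird 2 (980 higher and 805 lower). DESeq2 called 495 higher and 166 lower in that contrast, so the balance depends on the fit. The library of PR bird 22 had a high density of counts on the last exon (log2 of last exon over 5′ part -0.355, against -1.28 to -0.792 in the other 15). Without it 0 genes passed in SP against PR and 1 over the 4 states, and FKBP5 alone of the 6 kept its call (adjusted p = 0.0489).

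No pineal gene passed by edgeR in PI against SP (550 genes at an unadjusted p under 0.05, 30 by DESeq2) or in BR against PI (2044 and 439). In the latter 114 did without SP bird 2, and in the former 4 without SP bird 4. In PI against SP NR1D1 had 4.37 ± 0.911 against 0.640 ± 0.427 CPM (SD, n = 4 each, adjusted p = 0.34) and CIART 5.24 ± 0.32 against 1.51 ± 0.819 CPM (adjusted p = 0.467). Lists that were lower were heat shock (12 of 13, median -0.57, camera adjusted p = 2.3e-11; 7 adjusted over the list alone) and mural and fibroblast (9 of 9, -0.63, adjusted p = 0.000116). Also lower were mature neuron (11 of 12, -1.13, adjusted p = 0.00213; 2 adjusted over the list alone) and immediate early genes (13 of 14, -0.24, adjusted p = 0.00302). CAMK2A of neurons had 0.407 ± 0.28 against 10.5 ± 17.4 CPM. Called higher were the clock list (12 of 22, 0.02, adjusted p = 0.0214; 4 adjusted over the list alone) and pinealocyte markers (6 of 10, 0.04, adjusted p = 0.0237). So were melatonin synthesis and reception (6 of 9, 0.03, adjusted p = 0.0468) and visual phototransduction (adjusted p = 0.0241), whose median was -0.02 and mean 0.17. None of the 8 kept its call (adjusted p = 0.535 to 0.791 with an estimated correlation).

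In BR against PI the pineal gland was lower in all 13 mitochondrially encoded genes (median log2 difference -0.66, camera adjusted p = 6.5e-07; 3 adjusted over the list alone), with ND6 at 15.4 ± 7.89 against 76.5 ± 6.53 CPM (SD, n = 3 and 4). It was lower in mural and fibroblast markers (8 of 9, -1.0, adjusted p = 0.000669; 6 adjusted over the list alone), with COL1A2 at 148 ± 50.02 against 1034 ± 1087 CPM. All 13 heat shock genes were higher (0.42, adjusted p = 4.1e-05; 4 adjusted over the list alone), with HSP90AA1 at 3760 ± 695 against 1820 ± 337 CPM. In PR against BR mitochondrial (13 of 13, 0.23, adjusted p = 0.000669) and mural (8 of 9, 0.65, adjusted p = 0.000924) genes were higher. Lower were glucocorticoid response (8 of 12, -0.27, adjusted p = 0.00267; 1 fell over all genes and 3 adjusted over the list alone) and heat shock genes (12 of 13, -0.27, adjusted p = 0.00605). None of these 7 calls held (adjusted p = 0.718 with an estimated correlation, 0.752 for mitochondrial genes in PR against BR).

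SP against PR in the pineal gland was lower in the clock list (17 of 22, median log2 difference -0.23, camera adjusted p = 0.00223; 2 fell over all genes and 4 adjusted over the list alone) and tanycyte and ependyma markers (13 of 16, -0.58, adjusted p = 0.00223; 5 adjusted over the list alone). Also lower were pinealocyte markers (10 of 10, -0.67, adjusted p = 0.00267), visual phototransduction (15 of 24, -0.20, adjusted p = 0.00585; 4 adjusted over the list alone) and melatonin synthesis and reception (9 of 9, -0.45, adjusted p = 0.0496). Higher in SP were mural and fibroblast markers (9 of 9, 1.07, adjusted p = 0.000243; 5 adjusted over the list alone) and cell cycle genes (16 of 18, 0.38, adjusted p = 0.00302; 1 adjusted over the list alone). So were immediate early genes (13 of 14, 0.53, adjusted p = 0.00302; 4 adjusted over the list alone), with FOS at 13.6 ± 6.36 against 4.33 ± 0.593 CPM, and mitochondrially encoded genes (13 of 13, 0.34, adjusted p = 0.0197; 1 adjusted over the list alone). None of the 9 kept its call (adjusted p = 0.611 to 0.814 with an estimated correlation).

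The heat shock and unfolded protein list was lower in PI than in SP in the 3 tissues and higher in SP than in PR in the hypothalamus and the retina (pineal gland, median log2 difference 0.16, camera adjusted p = 0.109). Both contrasts use the same SP libraries. None of these 5 calls held (adjusted p = 0.303, 0.598 and 0.535 with an estimated correlation in PI against SP in hypothalamus, retina and pineal gland, 0.306 and 0.688 in SP against PR in hypothalamus and retina). Whether the tissues differ in this change was tested gene by gene. In PI against SP 0 of the 13 members had a change that differed between 2 tissues by edgeR (median difference -0.19 in the retina and -0.11 in the pineal gland against the hypothalamus). In SP against PR 0 did between retina and hypothalamus (median difference 0.26), 1 between pineal gland and hypothalamus (-0.30) and 2 between pineal gland and retina (-0.63). In BR against PI 2 did between pineal gland and retina (0.71), where no gene passed with the bird as a replicate block. Over all genes, 1729 had a change that differed between 2 tissues in at least 1 of 12 tests. In SP against PR between the pineal gland and the retina 1148 did (657 higher and 491 lower, or 815 and 372 with size factors), and 85 with the bird as a replicate block (34 higher and 51 lower). The 1729 genes became 198 with the block, which was fitted for each pair of tissues on the birds with both, and 3091 without SP bird 2.

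**Figure D5:**
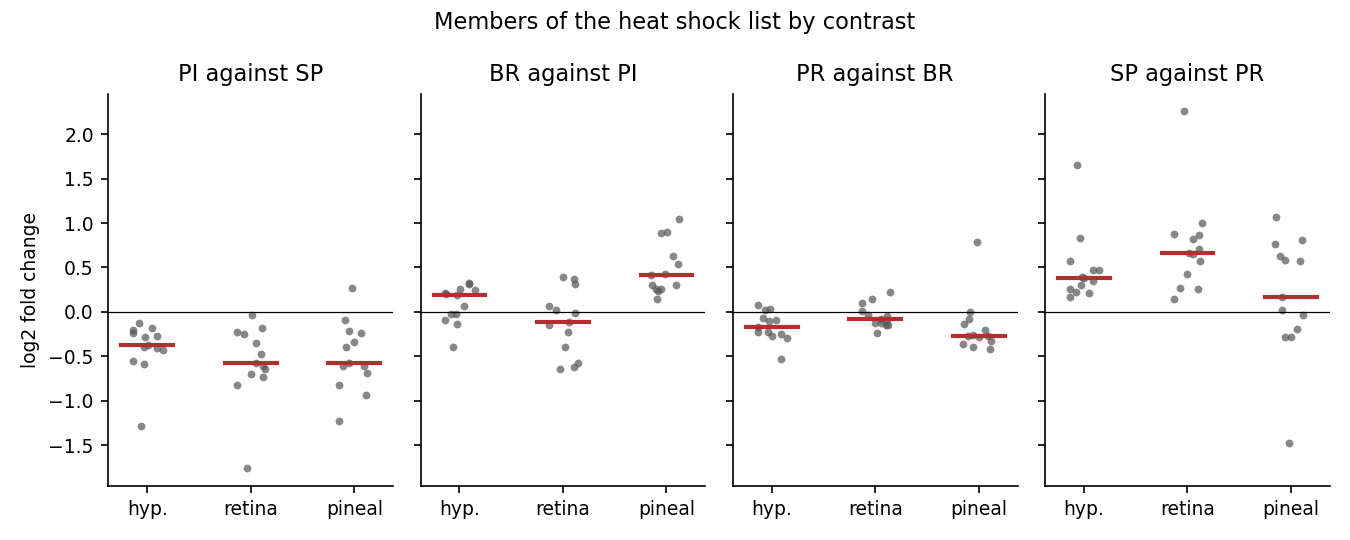
Log2 differences of the 13 measured members of the heat shock and unfolded protein list in each tissue (hypothalamus, retina, pineal gland) and contrast of states. Points are genes and the red line is the median, which in PI against SP was -0.37 in the hypothalamus and -0.57 in the retina and in the pineal gland.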

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

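In the retina comparison of BR with PI, the removal of 5 libraries and the sets of left-out libraries were chosen after its result was seen, while the W-chromosome covariate had been set beforehand and was taken as a test of it afterwards. Single birds stood apart from their group by Dixon's test in 30 of 274 groups of named genes and in 4 of 21 groups of VA opsin, where chance gives about 1 in 20.

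In the hypothalamus the birds apart were PR bird 20 for ARNTL (52.4 CPM), BR bird 14 for CIART (0.437), SP bird 1 for GNRH1 (15.7), PI bird 8 for NR1D1 (2.53), SP bird 3 for PER3 (33.6), PI bird 11 for ALDH1A1 (215.5) and SP bird 4 for RGS2 (13.9). For VA opsin they were PI bird 9 (20.6 CPM), BR bird 15 (13.7 CPM), PI bird 10 (upstream share 83.8%) and, in the pineal gland, PR bird 22 (upstream share 6.38%).

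In the retina SP birds stood apart for KIF4A (bird 1, 3.27 CPM), JTB (bird 1, 30.02), MYOF (bird 5, 38.6), ABCB1 (bird 3, 3.64), FGL2 (bird 3, 8.22) and SERPIND1 (bird 3, 2.73). PI birds did for CGA (bird 9, 1.21), DDC (bird 10, 74.02), KIF4A (bird 7, 69.2), PHGDH (bird 11, 86.5), ACTA1 (bird 7, 3.77), ABCB1 (bird 13, 0.913), DCN (bird 12, 5.76), HSPA2 (bird 8, 174) and PEROPSIN-like (bird 13, 247). BR birds did for CNGB1 (bird 16, 681.5), HSPA4L (bird 16, 590.7), ACTA1 (bird 15, 46.1), MYOF (bird 14, 63.1) and COL3A1 (bird 15, 8.06), and PR birds for BOLA3 (bird 22, 4.07), ANXA1 (bird 20, 56.7) and COL3A1 (bird 20, 24.5).

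Changes that differed between 2 tissues were counted in 12 tests. Between retina and hypothalamus they were 30 genes in PI against SP, 8 in BR against PI, 28 in PR against BR and 108 in SP against PR. The pineal gland differed from the hypothalamus in 59, 151, 8 and 233 genes in the same order, and from the retina in 146, 622, 45 and 1148 genes. Libraries of 2 tissues come from the same birds, and with the bird as a replicate block, in separate fits of each pair of tissues on the birds with both, the counts were 52, 3, 1 and 117 between retina and hypothalamus, 0, 0, 0 and 1 between pineal gland and hypothalamus, and 4, 0, 0 and 85 between pineal gland and retina.

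The 3203 retina genes that differed between BR and PI were weighed against 2 technical explanations, end bias of 5 libraries and the sex makeup of the groups. Without the 5 libraries 340 genes passed, and the median log2 difference of the genes that had risen went from 0.54 (median SE 0.16) to 0.33 (median SE 0.11). These genes were picked by the fit of all libraries, and the fall was not measured for other sets. It thus cannot tell end bias from this choice of genes. End bias may account for part of the calls, which these values do not settle. Of the 1979 genes that had fallen 196 still passed, and all that were tested kept their direction. Both fits share the BR libraries and part of the PI libraries, so the kept direction is little evidence. Leaving out 20 random sets of 2 SP and 3 PI libraries gave 83 to 6945 genes (median 2943), but these sets overlap the 5 libraries: those with 0 to 2 of them gave 1611 to 6945 genes and those with 3 or 4 gave 83 to 5123, and the 1 set as low as 340 held 3. With the level of W-chromosome genes as a covariate 3133 genes passed, which argues against sex makeup as the cause of most of the 3203 calls. Without the 5 libraries the same covariate left 143 genes in place of 340, so sex makeup stays open for those 340. A difference between the states, which the design names, stays open for them as well.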

How the results depend on the processing

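The fits without or with a term for the 5 retina libraries, without pineal bird 22, on the single highest exon and on distinct exons were tests chosen after the data were seen. Size factors, no filter, a 1 CPM filter, distinct exons and the removal of transthyretin left every total of higher and lower genes within 1.5 times. By direction, the 5 falls of PI against SP in the hypothalamus became 3 with no filter and 2 with the 1 CPM filter (7 rises) or distinct exons (7 rises). In PR against BR distinct exons gave 1 rise in place of 2. Of the changes that differ between tissues, the 4 that were higher for pineal gland against hypothalamus in PI against SP became 2 with size factors, no filter or no transthyretin. With the 1 CPM filter 5 higher between retina and hypothalamus in BR against PI became 3, and 5 lower in PR against BR became 3. The VA opsin exons with enough counts for a test alone (7 of 9 in the hypothalamus, 5 in the retina and 5 in the pineal gland) left the level by state short of the threshold, and a minimum of 1000 UMIs left the share in oligodendrocyte-like nuclei within its interval (54.2%). A minimum of 30 counts or of 5 long reads removed no library and no VA opsin model, so it tests nothing. With the bird as a replicate block the changes that differ between tissues were 198 in place of 1729 and the calls of OPN5-like-a and RGR ended. These fits took each pair of tissues alone, the birds with both and 16023 to 16064 genes (16484 in the fit of all libraries), so the block is not the sole change. No other call of a named gene between tissues changed. DESeq2 called 73, 22, 59 and 201 such changes between retina and hypothalamus (PI against SP, BR against PI, PR against BR, SP against PR), 112, 332, 27 and 423 between pineal gland and hypothalamus, and 239, 1036, 107 and 1499 between pineal gland and retina. Without the 5 retina libraries those between pineal gland and retina in BR against PI fell from 622 to 202, and those between retina and hypothalamus from 8 to 4 in BR against PI and from 108 to 68 in SP against PR. Where a value moved and nothing else is said, the cause was not tested.

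DESeq2 called 410, 34, 218, 42 and 58 genes in the hypothalamus (4 states, PI against SP, BR against PI, PR against BR and SP against PR), where edgeR called 48, 13, 6, 18 and 7. In the retina it called 588, 43 and 2096 in PI against SP, PR against BR and SP against PR, where edgeR called 293, 0 and 1169, and in the pineal gland 1221, 30, 439, 45 and 661, where edgeR called 9, 0, 0, 1 and 6. A fit of only the 2 groups, which has fewer samples, called 4 and 3 genes in the hypothalamus (PI against SP, BR against PI), 106, 0 and 2631 in the retina (PI against SP, BR against PI, SP against PR) and 0 in the pineal gland (SP against PR). A surrogate variable gave 10 in the hypothalamus (BR against PI) and 791, 7, 53, 13 and 633 in the pineal gland. The W-chromosome covariate gave 1 (4 states) and 0 (PR against BR) in the pineal gland. Without the 5 retina libraries 2074 genes passed over the 4 states and 340 in BR against PI, and the p of the VA opsin share was 0.0291 (0.147 with them). A term for them gave 2399, 787 and 1291 (4 states, PI against SP, BR against PI), and their removal with the W-chromosome covariate 1554 (4 states) and 143 (BR against PI). Without pineal bird 22 the counts were 1 (4 states) and 0 (SP against PR), and the highest exon gave 1 in SP against PR. Of the 50 list calls 0 held with an estimated correlation. The share of VA opsin UMIs in oligodendrocyte-like nuclei was 53.3%, 48.4% with doublets kept and 55.7% at Leiden resolution 0.5.

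With single birds left out the counts ranged from 25 to 130, 6 to 13, 5 to 67, 5 to 23 and 3 to 16 in the hypothalamus (4 states, then the 4 contrasts), from 2565 to 4730, 191 to 388, 27 to 4461, 0 to 2 and 608 to 1448 in the retina, and from 0 to 1359, 0 to 4, 0 to 114, 0 to 6 and 0 to 1785 in the pineal gland. The 3 tissue contrasts ranged from 13117 to 13355, 13939 to 14107 and 14222 to 14368, and the changes that differ between tissues from 1180 to 3091. Adjusted p of the VA opsin level ranged from 0.611 to 0.884, 0.0747 to 0.285 and 0.27 to 0.739 in hypothalamus, retina and pineal gland, p of its upstream share from 0.00055 to 0.123, 0.0669 to 0.419 and 0.0366 to 0.333, and its tissue differences from -2.36 to -2.26, -0.90 to -0.57 and 1.40 to 1.74.

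Sign changes occurred only in values that had not passed; the largest rises and falls were named only if they kept 1 direction with each bird left out, so for them this is fixed by the rule. OPN4 in the pineal gland against the hypothalamus was -0.086 with the replicate block. With the highest exon VA opsin in the hypothalamus was -0.062 in PI against SP and 0.052 in BR against PI, and EPB42 in the retina 0.05 in PR against BR; with a surrogate variable ISL1 in the pineal gland was 0.37 in PI against SP. With single birds left out the ranges in the hypothalamus were -0.027 to 0.449 (GNRH1), -0.087 to 0.081 (VA opsin), -0.044 to 0.28 (NPVF) and -1.13 to 0.025 (NR4A3) in PI against SP, -0.10 to 0.24 (NPVF) in BR against PI, -0.028 to 0.402 (TSHB) in PR against BR and -0.123 to 0.059 (VA opsin) in SP against PR. They were -0.124 to 0.019 for EPB42 in the retina in PR against BR, and in the pineal gland -1.07 to 0.67 (ISL1) and -0.30 to 2.38 (PDE6H) in PI against SP and -0.016 to 0.687 (ND5) in PR against BR. Of the named genes that passed, 26 in the hypothalamus, 55 in the retina and 6 in the pineal gland, 12, 28 and 6 missed the threshold with some bird left out. With only the 2 groups compared 12 of 26, 21 of 54 and 6 of 6 missed it, and with the highest exon 7 of 26, 3 of 54 and 4 of 6. The W-chromosome covariate ended 0, 5 and 2 calls, a surrogate variable 0, 5 and 0, no filter 3, 2 and 0, the 1 CPM filter 2 of 24, 0 and 0, and distinct exons 3, 0 and 0. In the retina 22 of 55 missed it without the 5 libraries, 26 with the W-chromosome covariate as well and 7 with a term for them, and in the pineal gland 5 of 6 without bird 22. Depth limits VA opsin most in the retina, with 34 to 189 counts per library, against 274 to 677 in the hypothalamus and 107 to 523 in the pineal gland.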

Other observations

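The tests of free RNA, of NKX6-2 reads in the first exon, of handling and of the correlation of VA opsin with all 33 lists were chosen after the results were seen. In the hypothalamus nuclei the following genes of the photoperiodic, reproductive and opsin lists had their highest level in classes other than oligodendrocytes. They are examples without a tally of the lists, and no background of free RNA was taken off. DIO2 had 484 and 425 CPM in endothelium-like nuclei of matrix 1 and 2 and 26.1 and 27.1 CPM in oligodendrocyte precursor-like nuclei. TSHR (34.9 and 29.5 CPM) and INHBA (71.2 and 62.1 CPM) were highest in astrocyte-like nuclei, and PGR, the progesterone receptor, in oligodendrocyte precursor-like nuclei (82.03 and 70.7 CPM). EYA3 (327 and 457 CPM) and CGA (69.7 and 273 CPM) were highest in pituitary endocrine-like nuclei, and the thyroid hormone transporter SLCO1C1 (160 and 549 CPM) and PEROPSIN-like (38.7 and 87.0 CPM) in choroid plexus-like nuclei, of which matrix 1 held 12. Transthyretin (TTR) was seen in 98.9% of neuron-like nuclei of matrix 2, and erythrocyte-like nuclei had 3320 CPM of it there and 141 CPM in matrix 1, so its free RNA differed between the matrices. Each matrix was taken as 1 bird, so none of these values was tested.

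The VA opsin UMIs of oligodendrocyte-like nuclei were weighed against free RNA, reads of the neighbour NKX6-2 and transcription together with it. Free RNA would give all nuclei a like level, while the level was 7.34 times that of all other nuclei in the lower of the 2 matrices. Misassigned NKX6-2 reads would lie in the first upstream exon, which touches NKX6-2, and 74.3% of the UMIs lay outside it (1010 of 1360, exact interval 71.9 to 76.6). Of those outside it, 49 lay in upstream exon 2 and 217 in annotated exon 2. NKX6-2 itself was 5.93 times higher in oligodendrocyte-like than in all other nuclei, consistent with transcription of both genes in these cells. That the 2 genes are transcribed together from a shared start remains a hypothesis. Higher levels of both in the same class of nuclei cannot tell it from separate transcription in the same cells.

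In the bulk hypothalamus the level of VA opsin rose with the mean of the oligodendrocyte and myelin list over 22 birds (7 members; Pearson r = 0.611, permutation p = 0.00268; Spearman rho = 0.597, permutation p = 0.00419). It was 0.624 without the 2 birds farthest on the list and 0.58 after state means were taken out. VA opsin also correlated with NKX6-2 (r = 0.595, permutation p = 0.00358; rho = 0.566, permutation p = 0.00708), and NKX6-2 with the list (r = 0.873, rho = 0.842, each with a permutation p of 1e-05, the smallest they can give). Adjusted over these 3 relations the p-values of r were 0.00358, 0.00358 and 3e-05. The oligodendrocyte content of a library may thus set part of its VA opsin level. Of all 33 lists this one ranked 1 by r (adjusted p = 0.0762 over the lists), followed by astrocyte (r = 0.544, adjusted p = 0.152), and no list passed that adjustment.

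The lower heat shock list in PI than in SP was weighed against end bias, sex makeup and handling. Without the 5 retina libraries with high last-exon density the retina list was still lower (camera adjusted p = 2.4e-12, median log2 difference -0.77), and with the W-chromosome covariate so was the hypothalamus list (adjusted p = 2.0e-14), which argues against the first 2 as the whole cause of the lower values. With an estimated correlation, which allows for genes that move together between birds, neither passed (adjusted p = 0.769 and 0.448), nor did the lists without these changes (adjusted p = 0.598 in the retina and 0.303 in the hypothalamus). Handling or sampling that differed between groups of birds cannot be told apart from state, because each state is 1 group of birds and no second group was measured. A response to state is a hypothesis that these data leave open.

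Other splits of the birds into groups of the same sizes were fitted to ask how often they call as many genes. The number of splits with as many genes includes the real one. In the hypothalamus no other split called as many over the 4 states (48 genes, highest other split 9), in BR against PI (6 and 1), PR against BR (18 and 1) and SP against PR (7 and 2), each with 1 of 50 splits. In the retina none did over the 4 states (3848 and 38) or in SP against PR (1169 and 420), each 1 of 50. In PI against SP 4 of 50 splits did (293 and 7359), so chance is not excluded there. In the pineal gland 4 of 50 did in SP against PR (6 and 730), so chance is not excluded there either. The real count was 0 in PR against BR in the retina (50 of 50, highest other split 13). It was also 0 in the pineal gland in PI against SP (35 of 35, 317) and BR against PI (35 of 35, 0). Every split reaches a count of 0, so these tests decide nothing. In a further 4 tests 2 of 50 splits reached the real count. That is a share under 0.05, but another split gave more genes, so chance is not firmly excluded: PI against SP in the hypothalamus (13 and 65), BR against PI in the retina (3203 and 6501), and the 4 states (9 and 362) and PR against BR (1 and 476) in the pineal gland. For the 3 tissue contrasts no other split called as many, with 1 of 25 each (13357 and 8518, 14124 and 11093, 14312 and 10006). For the changes that differ between tissues 2 of 25 did (1729 and 1738), so chance is not excluded there. The tests were not adjusted for their number. A share of 1 of 50 or 1 of 25 is the smallest that these splits can give, and it does not by itself exclude chance. Splits called several times the real count in PI against SP in the 3 tissues and in the pineal gland over the 4 states, in PR against BR and in SP against PR. They may reflect a structure of the samples other than state, and which one was not tested.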
